A study of Mus musculus with 14 samples.

How the data were processed

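RNA was measured in 14 whole mouse fetuses of gestational day 12.5 that had been injected as zygotes, at random, with nuclease-free water (vehicle) or with a mimic of the microRNA let-7f-5p at a concentration the labels call stress-relevant, and had been carried by CD1 recipient dams. Poly-A selected RNA was made into libraries with a strand-specific TruSeq kit, per the labels' protocols. Group and sex came from the sample titles: 5 vehicle females, 4 vehicle males, 3 let-7f females and 2 let-7f males. No label ties a fetus to a litter or dam, so fetuses of 1 group may share a dam, and p-values measure the spread between these fetuses.

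The submitters' processing notes name Trimmomatic 0.39, kallisto 0.50.1, FastQC 0.12.1, MultiQC 1.28, DESeq2 1.48.2 and the genome build GRCm39, with no role or order. The authors deposited a normalized signal per gene and library, described as normalized counts per the labels. In each library, 100% of the values lay within 1e-06 of a whole multiple of the smallest value above 0 (largest distance 1.16e-10), so each value is a whole number of reads divided by 1 factor per library. Those reads were recovered for use in count models. They came to between 27709934 (let-7f male 1) and 42898166 (let-7f female 1) per library, and 1 read was worth between 0.794 and 1.07 units in every library except let-7f male 1, where it was worth 1.76. The table held 18132 named genes. A further 1 row without a gene name was left out; it held between 0.0180% and 0.0334% of the reads of a library. Another 26 genes shared all their values with another gene. The reads of any 2 libraries of a group differed by more than sampling noise (chi-square per degree of freedom of at least 18.6 in each of 20 pairs), so no library was counted as a duplicate.

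Genes with a mean deposited value of at least 10 were tested, 17400 in all, leaving out 732. Values were transformed as log2(value + 1), so fold changes of low genes are understated. One model with a mean for each of the 4 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 10 residual degrees of freedom, and p-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. The comparisons were let-7f against vehicle in females, in males and as the mean over both sexes, the difference of the let-7f change between the sexes, and male against female among vehicle fetuses. Gene lists fixed before the data were examined, 43 in number, were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation and fry beside it. A list score is the mean over tested members of the log2 deviation from each gene's mean over the 14 libraries. Matches of 7 or 8 bases to the let-7 seed were sought in 3' UTRs of the GENCODE M21 annotation on GRCm38, an older build than the authors named; 15482 of the tested genes (88.98%) had such a UTR. Copies of a gene were sought with BLAST+ 2.17.0+.

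Named genes followed a rule fixed before the data were examined. It took genes past the threshold with a mean value of at least 50, an established symbol and, for let-7f comparisons, every let-7f library on the same side of the vehicle mean of its sex, up to 10 in each direction. Where under 5 genes passed, it also took the 5 smallest p-values in each direction. It further took the 4 members with the smallest p of each list past the threshold, 2 of other lists described, and a fixed set of let-7, growth and sex-linked genes. Of that set, H19 and Xist were not analysed here. Gm2436, Gm26992, Rpl36a-ps1, Gm19220, Aloxe3 and, for the difference between sexes, Grip2 fall outside the rule and were named after their values were seen.

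The alternatives were pseudocounts of 0.5 and 5, no filter and a mean of at least 50, rescaling to the 75th percentile, a robust spread model, library weights, only the groups compared, the replicate number as a block, leaving out each library in turn, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 (Wald) on the recovered reads. Alternatives chosen after seeing the data were leaving out 5 libraries that stood apart, adding ribosomal protein and liver scores as covariates, and testing the lists for the difference between sexes and for sex. Those 5 were vehicle males 1 and 2, vehicle females 1 and 2 and let-7f male 1. Each had a ribosomal protein score above 0.3, a liver score below -2 or a trophoblast score above 1. The limma procedure was tested on counts simulated from the real means, dispersions and library sizes, with 200 of 17400 genes changed. Each gene was drawn independently, so shifts of many genes together in a library were absent, and the shares may differ in the real data. In the female comparison it recovered 27% of genes changed by 2-fold and 86% of those changed by 4-fold. The corresponding shares were 15% and 76% in males, 51% and 95% over both sexes, 5% and 51% for the difference between sexes, and 42% and 86% for sex in vehicle fetuses.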

Results

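Gene expression was measured by poly-A RNA sequencing in whole E12.5 mouse fetuses of the strain F1 C57BL/6Jx129S1/SvlmJ. The fetuses developed from zygotes injected with vehicle or with a mimic of let-7f-5p, a small RNA of the let-7 family that represses transcripts carrying matching sites. The groups were 5 vehicle females, 4 vehicle males, 3 let-7f females and 2 let-7f males. The recovered reads ranged from 27709934 in let-7f male 1 to 42898166 in let-7f female 1. The question the series title poses is whether let-7f at the zygote stage alters development in a sex-dependent way. Values are the deposited normalized values, and changes are on the log2(value + 1) scale.

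The sex of the vehicle fetuses was compared first, since it checks the labels. The Y-linked gene Eif2s3y, which encodes a translation initiation subunit, had a value of 3448 ± 398 (SD, n = 4) in vehicle males and 2.76 ± 1.57 (SD, n = 5) in vehicle females. Kdm5d, a Y-linked histone demethylase, stood at 2397 ± 523 in males and 207 ± 12.9 in females. Ddx3y (log2 difference 7.20, SE 0.541, limma adjusted p = 3.27e-05) and Uty (3.71, SE 0.285, adjusted p = 3.27e-05) were also higher in males. The X-linked counterpart Eif2s3x, which escapes X inactivation, was lower in males, at 6807 ± 501 against 11513 ± 576 (log2 difference -0.76, SE 0.116, adjusted p = 0.0472). All let-7f males likewise carried high Eif2s3y (mean 3648) and all let-7f females low Eif2s3y (mean 5.68). In all, 7 of 17400 genes differed by sex among vehicle fetuses, 4 higher and 3 lower in males; edgeR called 5 and DESeq2 12.

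**Figure D1:**
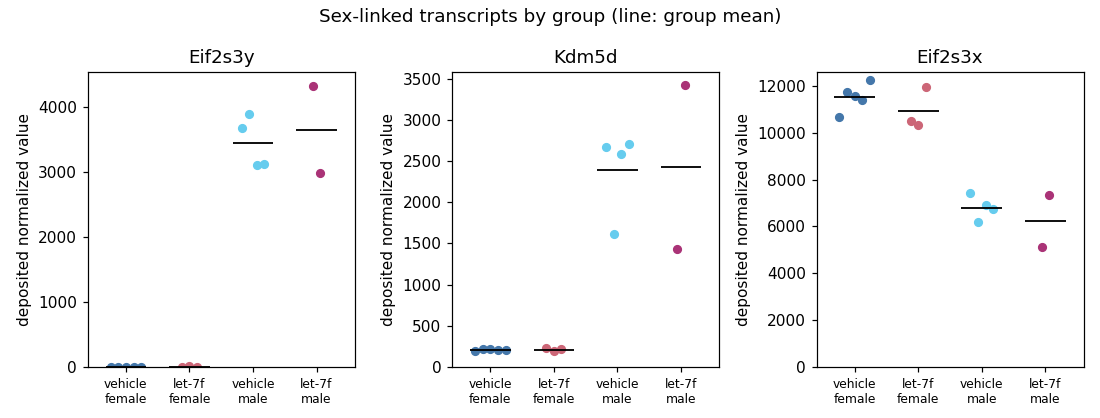
Deposited normalized values (vertical axis) of Eif2s3y, Kdm5d and Eif2s3x in each library, by group, with a line at each group mean. Eif2s3y averaged 3448 in vehicle males and 2.76 in vehicle females, and Eif2s3x averaged 6807 and 11513.

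The remaining genes that differed by sex were Gm26992 and Rpl36a-ps1, both lower in males and both named after their values were seen. Gm26992 lies on chromosome X from 103422010 to 103481705 on the plus strand (GRCm38, GENCODE M21) and overlaps Xist, which lies on the minus strand from 103460366 to 103483254. Its value was 269 ± 165 (SD, n = 5) in vehicle females and 1.69 ± 1.26 (SD, n = 4) in vehicle males; whether the counting used strand is not given in the sources used here, so reads of Gm26992 and Xist may not be separated. Rpl36a-ps1, named as a pseudogene of Rpl36a with which it may share reads, was at 0 in every vehicle male and at 38.4 ± 22.2 in vehicle females, at least 13.6-fold higher against a floor of 3 reads per library. In let-7f males, Rpl36a-ps1 averaged 194 with an SD of 239. Among the fixed lists, the Y-linked genes were higher in males in 4 of 4 tested members (median log2 difference 5.46, adjusted p = 1.73e-05 with an estimated correlation). The genes escaping X inactivation were lower in 6 of 6 (median -0.58, adjusted p = 0.00285 with an estimated correlation). In all, 19 lists passed for sex with the preset correlation and 2 with an estimated one, in a test added after seeing the data. The let-7 target list was among the 19, lower in vehicle males in 41 of 54 members (median -0.10, camera adjusted p = 0.00309). With an estimated correlation its camera adjusted p was 0.532. Without vehicle male 2 its median turned to 0.0392 (camera adjusted p = 0.851). Vehicle fetuses thus also differed in let-7 targets, in a way that depended on that library.

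In females, let-7f and vehicle fetuses differed in 1 gene, Gm2436, a pseudogene on chromosome 12 from 55142109 to 55151007 (GRCm38). It was named after its values were seen. Its value was 191 ± 146 (SD, n = 5) in vehicle females and 0 in each of the 3 let-7f females, at least 73.5-fold lower against a floor of 3 reads per library (limma adjusted p = 0.0168). Gm2446, a copy identical over 771 of 774 bases, had 241 to 357 in let-7f females and 0 to 255 in vehicle females (log2 change 2.98, 95% interval -1.32 to 7.29), and the sum of both was 309 ± 62.2 in vehicle and 297 ± 57.9 (SD, n = 3) in let-7f females. The log2 change of that sum was -0.06 (95% interval -0.479 to 0.366). Ppp2r3c also matched Gm2436, at 99.5% over 774 bases, and the log2 change of the sum of all 3 was -0.04 (95% interval -0.26 to 0.178). Reads of such copies cannot be assigned with certainty, so the value of Gm2436 alone is uncertain. edgeR called 0 genes in this comparison and DESeq2 2, and 141 genes had an unadjusted p under 0.05 in limma, where 870 would arise by chance from independent genes. The call of 1 gene was lost (0 genes) without vehicle female 2 or 3, or without let-7f female 1, 2 or 3.

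**Figure D2:**
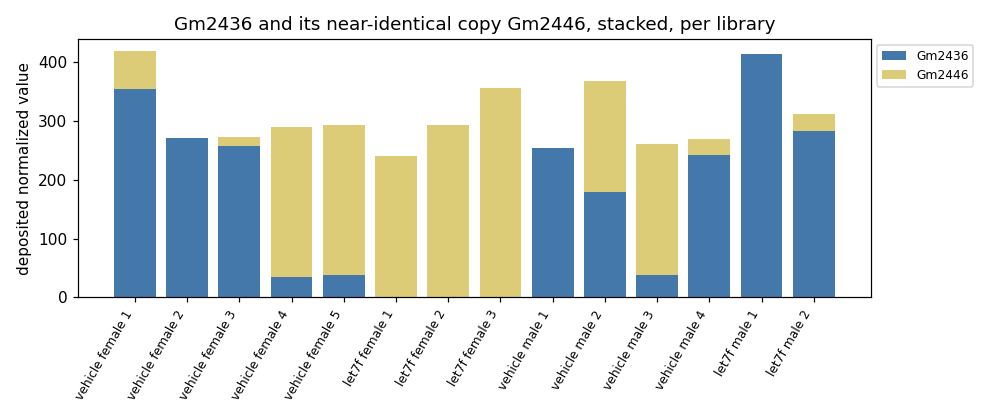
Stacked deposited normalized values of Gm2436 and Gm2446 (vertical axis) in each of the 14 libraries, ordered by group. Gm2436 is at 0 in the 3 let-7f females while the sum of both genes averages 297 there and 309 in vehicle females.

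Among genes that met the rule for named genes, the others with the smallest p in females did not pass (limma adjusted p = 1 for each). Rbm24, which encodes an RNA-binding protein of muscle, had 752 ± 150 (SD, n = 3) in let-7f and 360 ± 44.5 (SD, n = 5) in vehicle females. Rerg, a growth inhibitor related to Ras, had 163 ± 29.2 against 98.8 ± 10.8. Slc26a7 had a log2 difference of 1.10 (SE 0.318), Padi2 of 1.02 (SE 0.313) and Manba of 0.53 (SE 0.155). On the lower side, Lrrc23 had -1.22 (SE 0.328), Vdr, the vitamin D receptor, -1.68 (SE 0.585), Bhlhe23 -0.73 (SE 0.217), Hmgn2-ps -0.40 (SE 0.121) and Apba2 -0.40 (SE 0.133).

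Of the 43 gene lists, 10 passed in females with the preset correlation, 5 towards higher and 5 towards lower values, and 0 with an estimated correlation (smallest adjusted p = 0.735) or with fry. Without let-7f female 2, 5 lists passed. No list member was called, over all genes or adjusted over the list alone (0 in each). Liver genes lay higher in let-7f females in 28 of 29 members (median log2 change 1.23, adjusted p = 1e-07, and adjusted p = 0.774 with an estimated correlation), for example Cps1, of the urea cycle (0.91, SE 0.512), and Apoh (1.88, SE 1.21). Erythroid genes lay higher in 23 of 23 (median 0.36, adjusted p = 0.774 with an estimated correlation), including Slc4a1, the red cell anion exchanger (0.66, SE 0.417). Vehicle female 2 had a liver score of -4.87, and without it the median change was 0.12 for liver (adjusted p = 0.382) and -0.00387 for erythroid genes (adjusted p = 0.811). With the 5 libraries that stood apart left out, an alternative chosen after seeing the data, 9 of the 10 lists kept their call, liver genes among them (median 0.27, adjusted p = 0.0021). The 5 were chosen in part by their liver and ribosomal protein scores, so the calls of those lists are not independent of that choice.

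Neural progenitor genes lay lower in 22 of 24 members in females (median -0.23, adjusted p = 0.735 with an estimated correlation), among them Sox3 (-0.55, SE 0.203) and Zic2 (-0.37, SE 0.204). Proliferation genes lay lower in 33 of 38 (median -0.10, adjusted p = 0.735 with an estimated correlation), such as Bub1 (-0.23, SE 0.135) and Top2a (-0.26, SE 0.165). Unfolded protein response genes lay lower in 22 of 28 (median -0.09, adjusted p = 0.774 with an estimated correlation), with Xbp1 at -0.37 (SE 0.142) and the chaperone gene Hspa5 at -0.47 (SE 0.191). Matrix genes lay higher in 26 of 29 (median 0.19) and skeletal muscle genes in 25 of 29 (median 0.20), both with adjusted p = 0.774 with an estimated correlation. Ribosomal protein genes lay lower in 78 of 79 (median -0.16, adjusted p = 0.821 with an estimated correlation) and respiratory chain genes in 73 of 76 (median -0.19, adjusted p = 0.797 with an estimated correlation). Interferon genes lay higher in 17 of 24 (median 0.14, adjusted p = 0.735 with an estimated correlation), with Ifit1 at 0.88 (SE 0.406). With each library left out in turn, 2 of the 10 lists kept their call every time, neural progenitors and the unfolded protein response. The median of the first was -0.127 without let-7f female 2, and that of the second -0.20 without vehicle female 2 or let-7f female 3. Ribosomal protein and respiratory chain genes lost it without vehicle female 1 (medians -0.05 and -0.08), let-7f female 1 (-0.09 and -0.13) or let-7f female 2 (-0.02 and -0.06). Matrix (0.08) and proliferation genes (-0.05) lost it without let-7f female 2, and skeletal muscle genes without vehicle female 3 (0.08). Interferon genes lost it without vehicle female 2 (0.07), 3 (0.14) or 5 (0.08), or let-7f female 2 (0.065) or 3 (0.23). Other medians moved by over 1.5 times with the call kept. Skeletal muscle genes had 0.38, 0.13 and 0.35 without vehicle female 1, 2 and 4, and interferon genes 0.22 and 0.21 without vehicle female 1 and 4. Ribosomal protein genes had -0.26 and -0.24 without vehicle female 2 and 3. Without let-7f female 3 the medians were -0.37 for ribosomal protein, -0.355 for respiratory chain, 0.37 for matrix and -0.18 for proliferation genes.

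In males, limma called 0 genes between 2 let-7f and 4 vehicle fetuses, with 1874 genes at an unadjusted p under 0.05. edgeR called 0 and DESeq2 58, of which 48 were higher in let-7f males. The value depended on the libraries: without let-7f male 2, which leaves let-7f male 1 alone and assumes that it varies like the other groups, limma called 4390 genes, and without vehicle female 5 it called 1. Let-7f male 1 stood apart, with 16.2% of its reads from ribosomal protein genes, against 4.89% in let-7f male 2, and 2.21% from Lars2, against 0.0977% there and 0.0416% to 1.39% in the vehicle libraries.

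The smallest p in males belonged to Rpl36a-ps1 (limma adjusted p = 0.138), named after its values were seen, whose SD in let-7f males exceeded its mean. Among genes that met the rule for named genes, those with the smallest p did not pass in limma either (adjusted p = 0.447 for each). Grip2 had 4622 in let-7f and 1406 ± 270 (SD, n = 4) in vehicle males. The embryonic globin gene Hba-x had 103492 ± 49032 (SD, n = 2) against 23968 ± 6447 (SD, n = 4), and Jkamp 1507 ± 142 against 976 ± 56.7. Pdzk1ip1 had a log2 difference of 1.40 (SE 0.303) and Robo3, an axon guidance receptor, of 0.60 (SE 0.13). On the lower side, the imprinted gene Klf14 had -1.52 (SE 0.308), Lhcgr -1.45 (SE 0.303), Rmdn2 -0.96 (SE 0.215), Bmp6, a bone morphogenetic protein, -1.17 (SE 0.263) and Cntn6 -0.81 (SE 0.188). Of the genes named here for males, DESeq2 called Rpl36a-ps1, Grip2, Hba-x, Jkamp, Pdzk1ip1, Robo3, Klf14, Lhcgr, Rmdn2 and Cntn6. It did not call Bmp6.

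In males 10 lists passed with the preset correlation, 7 towards higher and 3 towards lower values, and 0 with an estimated correlation (smallest adjusted p = 0.841) or with fry. Without let-7f male 2, 6 lists passed. Over all genes 0 members were called, and 16 when adjusted over the list alone. The 3 embryonic globin genes lay higher (median log2 change 2.07, adjusted p = 0.841 with an estimated correlation), with Hbb-bh1 at 2.72 (SE 0.639) and Hbb-y at 1.23 (SE 0.433). Matrix genes lay lower in 26 of 29 (median -0.53, adjusted p = 0.841 with an estimated correlation), among them Col14a1 (-1.02, SE 0.291), Lox, which crosslinks collagen (-1.13, SE 0.346), and Col1a1 (-0.84, SE 0.27). Cartilage genes lay lower in 19 of 24 (median -0.49, adjusted p = 0.941 with an estimated correlation), including Matn3 (-2.07, SE 0.525) and Acan, the main cartilage proteoglycan (-1.32, SE 0.484). Proliferation genes lay higher in 32 of 38 (median 0.23, adjusted p = 0.841 with an estimated correlation), with E2f1 at 0.61 (SE 0.216), and neural progenitor genes in 17 of 24 (median 0.16, adjusted p = 0.941 with an estimated correlation), with Neurog1 at 1.25 (SE 0.364). Embryonic globin and matrix genes were the 2 lists that kept their call with each library left out in turn, with a matrix median of -0.31 without let-7f male 1. Neural progenitor genes had a median of 0.35 without that library. Without let-7f male 2, proliferation (median 0.20), neural progenitor (-0.08) and cartilage genes (-0.54) lost it. Without vehicle male 2, neural progenitor (0.125) and cartilage genes (-0.395) did. The fits without let-7f male 1 or 2 rest on 1 let-7f male. Let-7f male 2 had an embryonic globin score of 0.577, above the vehicle males (-1.345 to -0.2315) but inside the range of vehicle females (-0.4376 to 0.784). Its matrix score of -0.1549 lay below the vehicle males (0.1503 to 0.1918) but inside the range of vehicle females (-0.2496 to 0.1444).

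The other 5 lists lost their call without let-7f male 1. Ribosomal protein genes lay higher in 79 of 79 (median 0.99), and their median without that library was -0.08 (adjusted p = 0.15). Respiratory chain genes lay higher in 73 of 76 (median 0.77, and -0.09 without it, adjusted p = 0.171). Heart muscle genes had a median of 0.60 (-0.03 without it), S-phase histone genes 1.21 (-0.35 without it) and the IGF and growth hormone axis -0.34 (-0.09 without it, adjusted p = 0.089). The medians without let-7f male 2 were 1.97 for ribosomal protein, 1.61 for respiratory chain, 1.26 for heart muscle and 3.22 for histone genes. The IGF axis had -0.21 without vehicle male 1 and lost its call without let-7f male 2 (-0.525), and histone genes lost theirs without vehicle male 1 (1.06), 2 (1.66) or 4 (1.01). With the 5 libraries that stood apart left out, which sets let-7f male 2 alone against vehicle males 3 and 4, 8 of the 10 lists kept their call. Ribosomal protein genes then had a median of 0.21 (adjusted p = 0.000102), respiratory chain genes 0.20 (adjusted p = 0.000118) and the IGF axis -0.16 (adjusted p = 0.0208), while heart muscle (0.11, adjusted p = 0.57) and histone genes (-0.47, adjusted p = 0.439) lost it. With an estimated correlation and all libraries, adjusted p = 0.941 held for each of these 5. The libraries left out were chosen in part by their ribosomal protein score, so the ribosomal protein values without them are not independent of that choice. In the IGF axis, Igf2, a fetal growth factor, had 53587 ± 1063 (SD, n = 2) in let-7f and 82934 ± 15343 (SD, n = 4) in vehicle males, with a log2 difference of -0.61 (SE 0.252, limma adjusted p = 0.447). Socs2, which restrains growth hormone signalling, had -0.38 (SE 0.157).

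**Figure D3:**
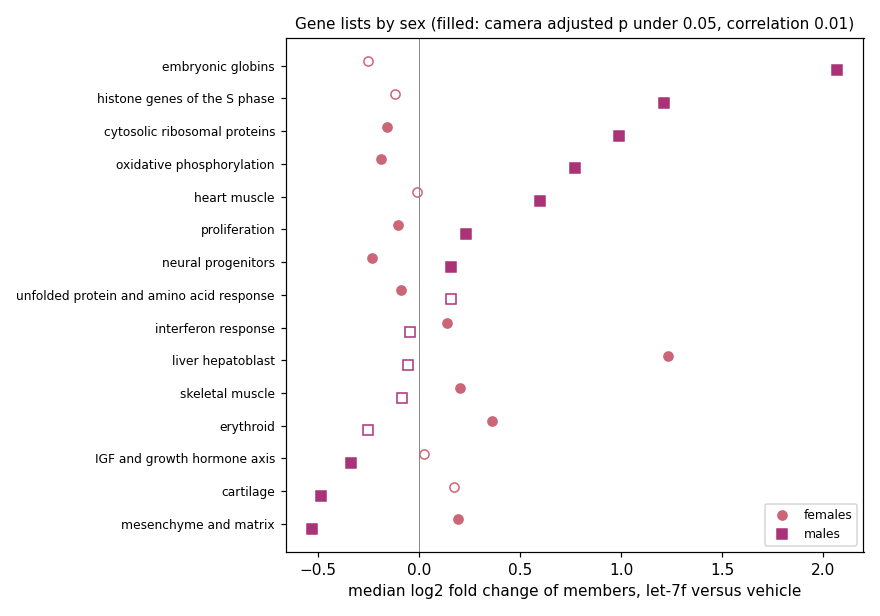
Median log2 fold change of list members, let-7f against vehicle (horizontal axis), for lists that passed in either sex with the preset correlation of 0.01; circles are females, squares males, and filled symbols passed. Ribosomal protein genes stand at 0.99 in males and -0.16 in females, and 0 lists passed in either sex with an estimated correlation.

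Averaged over both sexes, limma called 0 genes, with 483 at an unadjusted p under 0.05 and a smallest adjusted p of 0.947. edgeR called 0 and DESeq2 8, among them Gng4, Jkamp, Rpl36a-ps1 and Gm2436. Without let-7f male 2, limma called 874. The smallest p-values belonged to Rpl36a-ps1, Gm2436 and Aloxe3, named after their values were seen (limma adjusted p = 0.947 for each). Among genes that met the rule for named genes, they belonged to Gng4, a G protein subunit (log2 difference -1.61, SE 0.374), Itgal, a leukocyte integrin (-0.67, SE 0.156), Fam221a (-0.80, SE 0.197), Ocln, of tight junctions (-1.01, SE 0.26), Cadps2 (-0.82, SE 0.217), Jkamp (0.37, SE 0.0876), Itpr2 (0.67, SE 0.18), Pik3cg (1.02, SE 0.291), Rerg (0.47, SE 0.136) and Abca4 (0.44, SE 0.129). Of the lists, 8 passed with the preset correlation and 0 with an estimated one (adjusted p = 0.957 for each of the 8); 5 passed without let-7f male 2. Cholesterol synthesis genes lay higher in 19 of 23 (median 0.12), with Insig1 at 0.22 (SE 0.0931), and Hox genes in 29 of 39 (median 0.12), with Hoxc9 at 0.57 (SE 0.214). Ribosomal protein genes (median 0.39) and respiratory chain genes (0.31) turned to -0.13 and -0.14 without let-7f male 1, and both passed in that opposite direction. Embryonic globin (0.91), heart muscle (0.27), cartilage (-0.16) and matrix genes (-0.16) were the others. Without let-7f male 1, heart muscle genes turned to -0.05 (adjusted p = 0.746) and matrix genes lost their call (-0.08, adjusted p = 0.128). The embryonic globin median was 0.55 without that library, and the matrix median -0.08 without let-7f female 3. The medians without let-7f male 2 were 0.90 for ribosomal protein, 0.73 for respiratory chain, 0.595 for heart muscle and -0.26 for matrix genes, and respiratory chain genes had 0.48 without vehicle male 2. Of the 8 lists, 0 kept their call with each library left out in turn. Without let-7f male 2, embryonic globin (1.16), cartilage (-0.18), cholesterol (0.03) and Hox genes (0.18) lost it. Cartilage, cholesterol and Hox genes also lost it without vehicle male 2 (-0.14, 0.04 and 0.09) or vehicle female 1 (-0.14, 0.08 and 0.12). Cartilage genes did so without vehicle female 4 (-0.14) or let-7f female 3 (-0.09), cholesterol genes without let-7f female 2 (0.06) and Hox genes without vehicle female 2 (0.04) or let-7f female 3 (0.04). With 5 libraries that stood apart left out, an alternative chosen after seeing the data, 1 list passed and it was not among these 8 (0 kept).

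The difference of the let-7f change between males and females was tested directly. limma called 0 genes, with 1485 at an unadjusted p under 0.05, edgeR 0 and DESeq2 24. Without let-7f male 2, limma called 3206. The smallest p-values belonged to Gm2436 (limma adjusted p = 0.213), Gm19220 (0.213), Rpl36a-ps1 (0.25) and Grip2 (0.282), named here after their values were seen. Among genes that met the rule for named genes, they belonged to Klf14 (male minus female -2.02, SE 0.403), Slc26a7 (-2.14, SE 0.494), Cntn6 (-1.05, SE 0.246), Bnip3 (-0.60, SE 0.144), Hpcal4 (-1.82, SE 0.446), Robo3 (0.76, SE 0.17), Pdzk1ip1 (1.67, SE 0.396), the neural progenitor factor Sox3 (1.30, SE 0.314), Muc1 (1.40, SE 0.361) and Clpb (0.64, SE 0.166), each with a limma adjusted p of 0.522. Igf2 had -0.77 (SE 0.33). DESeq2 called Klf14, Slc26a7, Bnip3, Robo3, Pdzk1ip1, Clpb, Gm2436, Gm19220, Rpl36a-ps1 and Grip2 of those named. Under limma and edgeR, a gene that passed in 1 sex and not in the other is not shown to differ between them.

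Transcripts controlled by let-7 were examined as a group. Hmga2, a growth-related chromatin gene and let-7 target, had 12247 ± 1855 (SD, n = 3) in let-7f and 12989 ± 2428 (SD, n = 5) in vehicle females, a log2 change of -0.07 (SE 0.2), and of 0.15 (SE 0.238) in males. Lin28b, which blocks let-7 maturation, changed by -0.02 (SE 0.199) in females and 0.27 (SE 0.236) in males, Igf2bp1 by -0.08 (SE 0.251) and 0.24 (SE 0.298), Trim71 by -0.15 (SE 0.314) and 0.50 (SE 0.372), and Lin28a by 0.11 (SE 0.447) and 0.43 (SE 0.53); none passed. The list of 54 let-7 targets had a median change of -0.03 in females (adjusted p = 0.355) and -0.04 in males (adjusted p = 0.994), where its mean was 0.01. The female median lay above 0 without vehicle female 2 (0.018), 3 (0.0289) or 5 (0.00331) or let-7f female 3 (0.00552), and at -0.073 without let-7f female 1, none of which passed. The list passed towards lower values in females without vehicle female 1 (median -0.118, adjusted p = 0.00319) and with the 5 libraries that stood apart left out (-0.117, adjusted p = 0.00614), with adjusted p = 0.627 and 0.703 with an estimated correlation. In males its median turned to 0.149 without let-7f male 1, towards higher values and so against the direction of repression. Let-7f male 2 was then the only let-7f male, so only the size and direction are given. The male median was -0.256 without let-7f male 2 and -0.124 without vehicle male 2 (camera adjusted p = 0.324). It lay at -0.0172, -0.00301 and -0.0135 without vehicle male 1, 3 and 4. The list of let-7 control genes had a median of -0.0154 in females and 0.0568 in males (camera adjusted p = 0.635 and 0.616). Its male median was 0.148 without let-7f male 1. Among the growth genes, Dlk1 changed by 0.14 (SE 0.28) in females and -0.05 (SE 0.333) in males, Cdkn1c by -0.00 (SE 0.304) and -0.26 (SE 0.361), and Igf1 by 0.27 (SE 0.222) and -0.14 (SE 0.263).

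The 2615 tested genes with a let-7 seed match were compared with 12867 without. Their median log2 change differed by 0.04 in females, by -0.11 in males and by -0.04 over both sexes. Before adjustment the male difference passed the threshold of 0.05; adjusted over the 3 comparisons none did (camera in limma, adjusted p = 0.0726 in males, 0.121 in females and 0.121 over both sexes). With an estimated correlation the male value was adjusted p = 0.591. Genes with and without a match were not matched on UTR or transcript length. The deviation of let-7f male 1 from the other libraries fell with transcript length across genes (Spearman -0.365), and that of let-7f male 2 rose (0.151). An effect of length is therefore not separated from an effect of the sites. Without let-7f male 1 the male difference turned to 0.0221. Without vehicle male 1, 3 or 4 it no longer passed before adjustment, at -0.0654, -0.0777 and -0.0862. It was larger in size without vehicle male 2, at -0.202, and still passed before adjustment. It was -0.24 without let-7f male 2, where let-7f male 1 was the only let-7f male. The female difference passed before adjustment without vehicle female 2 (0.0687), vehicle female 3 (0.0622) or let-7f female 3 (0.0902). The difference over both sexes did so without vehicle male 2 (-0.0855), vehicle female 1 (-0.0612), let-7f male 2 (-0.107) or let-7f female 2 (-0.0532), and it turned to 0.0304 without let-7f male 1.

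**Figure D4:**
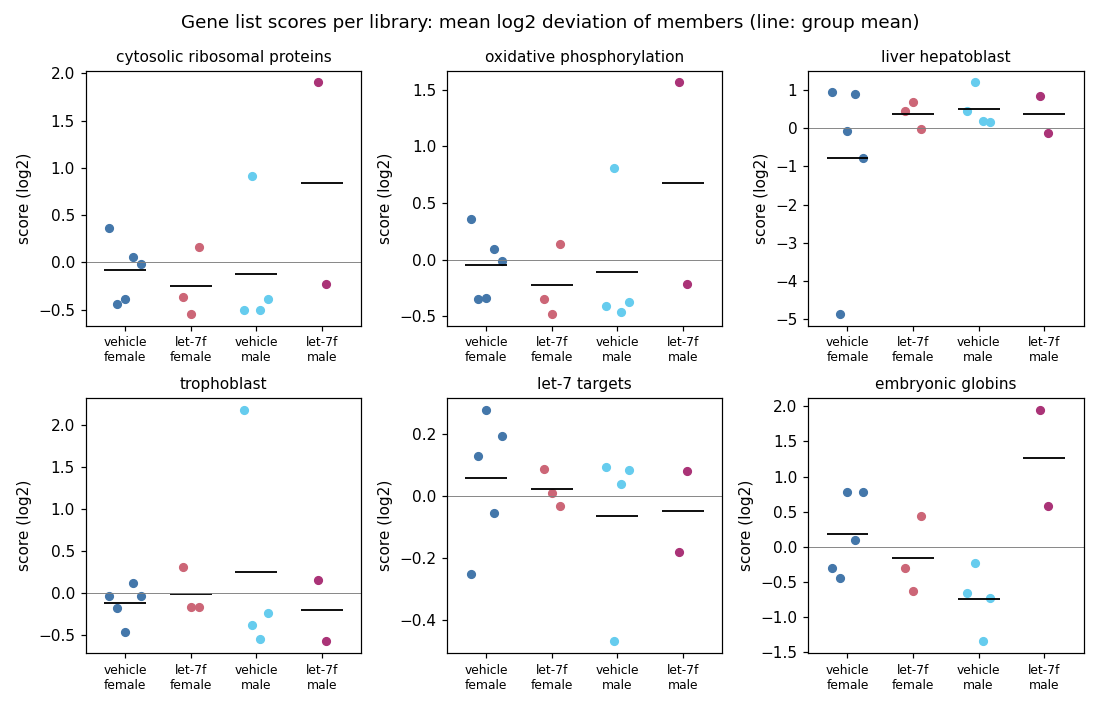
Scores of 6 gene lists (vertical axis, mean log2 deviation of the members) in each library, by group, with a line at each group mean. Let-7f male 1 has a ribosomal protein score of 1.90, vehicle female 2 a liver score of -4.87 and vehicle male 1 a trophoblast score of 2.19.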

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

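The test of whether both let-7f males share a change was chosen after the result was seen. A single library far from the rest of its group was sought in 198 group and measure combinations, where chance alone gives about 9.9 such findings. Only the vehicle groups were searched, because the let-7f groups were too small, so no let-7f library could be found this way. Such a library was found in 23 combinations, most of them in vehicle male 2. In that library, ribosomal protein genes took 9.76% of reads (4.20% to 4.41% in the other vehicle males), globins 3.35% and the top 10 genes 5.58%. Its scores were 0.91 for ribosomal proteins, 0.81 for the respiratory chain, 0.34 for heart muscle, 1.24 for eye and lens, 0.27 for the unfolded protein response, -0.47 for let-7 targets, -0.51 for let-7 control genes, -0.16 for cholesterol synthesis and -0.21 for limb patterning. Its log2 values were 12.9 for Hmga2, 15.3 for Cdkn1c, 10.7 for Kdm5d and 8.44 for Uty. Vehicle male 1 had scores of 2.19 for trophoblast and 1.17 for yolk sac endoderm. Vehicle female 2 had a Hox score of -0.77. Vehicle female 1 had log2 values of 6.75 for Lrrc23, 6.66 for Vdr and 11.9 for Robo3, and vehicle male 3 had 7.97 for Fam221a.

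The let-7f change differed between males and females in 13 lists by camera with the preset correlation and in 0 with an estimated correlation (smallest adjusted p = 0.497). As medians of the male minus female change, ribosomal proteins had 1.08 (adjusted p = 7.67e-14), the respiratory chain 1.0 (1.37e-11), proliferation 0.32 (1.28e-05), neural progenitors 0.38 (0.000304), embryonic globins 2.32 (0.000778), heart muscle 0.68 (0.00844) and S-phase histone genes 1.45 (0.0293). Those below 0 were matrix at -0.71 (1.61e-10), cartilage at -0.64 (0.000779), erythroid at -0.59 (0.00833), the IGF axis at -0.39 (0.0114), liver at -1.35 (0.0166) and skeletal muscle at -0.32 (0.0244). Embryonic globin and matrix genes were the 2 lists that kept this call with each library left out in turn. For both, the score of let-7f male 2 lay inside the range of the vehicle females. The call ended without let-7f male 1 for ribosomal proteins (0.0792), the respiratory chain (0.0894), heart muscle (0.0191) and histone genes (-0.154). Without let-7f male 2 it ended for the IGF axis (-0.47), erythroid (-0.832), liver (-0.905), neural progenitor (0.0928), skeletal muscle (0.138), cartilage (-0.681) and proliferation genes (0.248). Erythroid, liver and skeletal muscle genes also lost it without vehicle female 2 (-0.232, -0.196 and -0.269) or vehicle male 2 (-0.524, -1.10 and -0.152). Skeletal muscle genes did so without vehicle female 3 (-0.196) or 5 (-0.238), and histone genes without vehicle male 1 (1.34) or 4 (1.16), vehicle female 1 (1.23) or 4 (1.02), or let-7f female 2 (1.25). Other medians also moved. Without let-7f male 1 they were -0.14 for the IGF axis, -0.751 for skeletal muscle and 0.576 for neural progenitor genes. Without let-7f male 2 they were 2.09 for ribosomal proteins, 1.82 for the respiratory chain, 1.33 for heart muscle and 3.68 for histone genes.

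The 155 ribosomal protein and respiratory chain genes were high in let-7f male 1. Over the 140 with an annotated length, the median log2 deviation from the other libraries was 1.83. A let-7f effect common to both let-7f males stays open. The mean score of all 155 genes in let-7f male 2 was -0.222. That lay inside the range of all 4 vehicle males (-0.484 to 0.858) but above the 2 that did not stand apart (-0.484 to -0.38). Vehicle male 2 was set apart by its ribosomal protein score (0.909), and the same genes enter the score compared here. The narrower range is therefore not independent of that choice and cannot decide the question. An excess of short transcripts in let-7f male 1 is argued against as the whole cause. Genes outside the lists matched on length and mean value deviated by 0.376, a ratio of 0.205 to the members (95% bootstrap interval 0.144 to 0.253). The bootstrap drew genes of that library alone, so its interval does not measure the spread between fetuses. Part of the shift may still follow length, since the deviation of that library fell with transcript length across genes (Spearman -0.365), as it did in vehicle male 2 (-0.427) and vehicle female 1 (-0.366), whose ribosomal protein scores were only 0.91 and 0.37. A response of that fetus alone, its handling and its RNA quality remain open and were not tested.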

How the results depend on the processing

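Results are given as genes called unless another quantity is named, and alternatives not listed gave counts within 1.5 times the reported one; the cause of each change was not tested. In females (1 gene), the count was 0 with a pseudocount of 5, with the groups compared alone and with edgeR. It was also 0 with the 5 libraries that stood apart left out and with the covariates. It was 2 without a filter and with DESeq2, and 18 with library weights. Those weights were 14.2 for let-7f female 1 and 0.172 to 2.32 for the other libraries, so the 18 calls rest largely on that fetus. In males (0) the count was 1 with a pseudocount of 0.5 and 58 with DESeq2. DESeq2 gave 8 over both sexes, 24 for the difference between sexes and 12 for sex in vehicle. With an estimated correlation 0 lists passed in females, in males and over both sexes. Over both sexes 5 lists passed with library weights, 1 without the 5 libraries and 15 with the covariates. The seed-site difference in males was -0.0944 with 8-base sites, -0.0491 without the 5 libraries and 0.0581 with the covariates, where its direction reversed. With library weights the seed-site difference was -0.191 in males, 0.0539 in females and -0.0714 over both sexes. Each of these passed the threshold before adjustment. With the covariates the difference over both sexes was 0.0383, again reversed, and it passed before adjustment in that reversed direction. The 5 libraries and the covariates were chosen after seeing the data.

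Leaving out each library in turn gave 0 to 1 genes in females, 0 to 4390 in males, 0 to 874 over both sexes, 0 to 3206 for the difference between sexes and 5 to 7 for sex in vehicle. Lists ranged from 5 (without let-7f female 2) to 15 in females, 6 (without let-7f male 2) to 15 in males and 5 (without let-7f male 2) to 10 over both sexes. The seed-site difference ranged from 0.00239 to 0.0902 in females, -0.24 to 0.0221 in males, where it reversed without let-7f male 1, and -0.107 to 0.0304 over both sexes, reversed likewise. The highest gene counts in males, over both sexes and for the difference between sexes came without let-7f male 2, which leaves let-7f male 1 as the only let-7f male.

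No label says that the replicate numbers pair the fetuses. Deviations of same-numbered libraries correlated between -0.576 and 0.346, and 5 of 16 pairs lay above 0.1. Differently numbered libraries were not compared in this way, so these values cannot show whether the numbers pair the fetuses. With the replicate number as a block, 0 genes were called in females and the seed-site difference in males was -0.0843, no longer past the threshold before adjustment. At this depth and group size, the median 95% half-width of a log2 change was 0.519 in females and 0.616 in males, before adjustment. In simulated data, where genes varied independently, 27% and 15% of genes changed by 2-fold passed after adjustment. Most changes of that size were thus missed in the simulation, and the share missed in the real data was not measured.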

Other observations

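The tests on Gm2436 and the correlation of globin switching with let-7 targets were chosen after the results were seen. Adult globin scores differed between libraries of a group. Vehicle female 2 had an adult globin score of -2.88, and vehicle female 1 had 1.37. The 5 libraries that stood apart included 4 vehicle fetuses.

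Regroupings of the same libraries were used to ask whether chance can be excluded. In females, 4 of 56 regroupings called as many genes as the real 1 (highest of the others 1), 43 of 56 passed as many lists as the real 10 (highest 20) and 38 of 56 gave a seed-site difference as large as 0.04 (highest 0.178). Over both sexes, 74 of 100 drawn regroupings passed at least the real 8 lists (highest 21) and 61 gave a seed-site difference as large (real -0.04, highest 0.197). Chance is therefore not excluded for these results. For genes over both sexes the real count was 0, which all 100 of 100 regroupings reach by construction, so they say nothing about chance there. The highest of them called 7167 genes and put vehicle male 2 with let-7f male 1, which points to a structure of the libraries other than treatment. For sex in vehicle fetuses, 1 of 100 drawn regroupings, the real one, reached 7 genes (highest of the others 1), and chance is excluded.

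Gm2436 was at 0 in the 3 let-7f females. A fall of the joint output of Gm2436 and Gm2446 by 1 or more on the log2 scale is argued against, since the lower 95% bound of the log2 change of their sum was -0.479. The sum changed by -0.0561, and by -0.04 with Ppp2r3c added, which is consistent with reads being divided differently between near-identical copies; a smaller fall stays open. Gm2446 was itself at 0 in vehicle male 1, vehicle female 2 and let-7f male 1, so the division also varied within the vehicle groups. Sequence differences between fetuses in these copies were not tested.

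A candidate explanation for part of the spread between libraries is a spread of developmental stage between fetuses, since fetuses replace embryonic by adult globins and lose let-7 targets as they age. Over 14 libraries, the log2 ratio of adult to embryonic globins correlated with the let-7 target score (Pearson r = -0.584, permutation p = 0.0255; Spearman rho = -0.604, permutation p = 0.0247; adjusted p = 0.0319 for both over 5 relations). Without the 2 libraries farthest from the median ratio r was -0.51 (permutation p = 0.0856), so the relation rests in part on vehicle females 2 and 5, the first of which also had a low liver score. Within groups, as deviations from group means, r was -0.651 (permutation p = 0.012). The permutation shuffled these deviations freely, although centring ties those of a group together, so this p may be too small. Ribosomal protein content is argued against as the cause, since r was -0.814 (permutation p = 0.00035) after both measures were regressed on that score. The residuals were shuffled freely as well, so this p is approximate. A trend with transcript length was not tested as a cause and stays open. The let-7 target score was lowest in vehicle male 2, vehicle female 1 and let-7f male 1 (-0.47, -0.252 and -0.182). In the same libraries the deviation fell most steeply with transcript length (Spearman -0.427, -0.366 and -0.365). The let-7 target score is therefore not a measure of stage alone. Stage itself was not measured beyond the stated gestational day of 12.5.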
